A study of Mus musculus with 24 samples.

How the data were processed

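Poly-A RNA was sequenced from 24 libraries of cultured mouse forelimb buds, 4 for each of 6 groups: DMSO, 1 µM BPDP and 10 µM BPDP, each at 3 and 24 h. Groups were taken from the sample labels. The labels describe capture of mRNA on poly-T beads, random-hexamer cDNA and NEBNext adaptors. They do not say whether the libraries keep the strand of the RNA, so reads of overlapping antisense genes cannot be separated, and closely related genes (histone, keratin and ribosomal protein genes) may share reads.

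Per the submitters' processing notes, the reads were handled with CASAVA 1.8, STAR 2.5, HTSeq 0.6.1 and DESeq2 (version given as 2) on mm10. The authors deposited 5 pairwise tables. Their count columns hold raw read counts per gene and library, deposited by the authors without normalization. Their fold change columns hold the authors' log2 fold change of the first over the second group. Their significance columns hold the authors' p-value and adjusted p-value for each gene. Gene lengths in bases come from the same deposited tables. A further 50 columns of FPKM values and group means were not used, since the counts carry the same information per library. Counts of a library that occurs in several tables were compared, and 0 differed, so the tables were joined into 1 matrix of 25844 genes, in which 25 symbols belong to more than 1 identifier. No pair of libraries in a group was a near copy (lowest chi-square per degree of freedom 4.91). For GC content, the genes were matched by identifier to GENCODE vM21: 25490 had an entry, 25464 of them on the same chromosome and strand, and 17992 (70.6%) with identical coordinates. Coordinates in the text are those of the authors' tables.

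Total counts were 17308913, 17643060, 18451350 and 19369801 in the 3 h controls (replicates 1 to 4), 16515690, 18109956, 20823058 and 15630217 with 1 µM at 3 h, and 17366351, 19800595, 14165947 and 14409906 with 10 µM at 3 h. They were 17093724, 18315744, 19540189 and 19972395 in the 24 h controls, 17358251, 14887622, 18828843 and 17985241 with 1 µM at 24 h, and 19909986, 17795012, 16373611 and 15726057 with 10 µM at 24 h. The precision this gives is printed as standard errors beside the main fold changes.

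The groupings, comparisons, tests, gene lists, thresholds and most alternatives were set before the data were examined. Each treated group was compared with the control of its time, and the 24 h with the 3 h controls, in fits of the 8 libraries concerned. The test was edgeR 4.0.16 quasi-likelihood (robust) in R 4.3.3 with TMM scaling and filterByExpr (minimum count 10, minimum total 15). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Doses were compared with each other, and effects between times, by contrasts in 1 fit of all 24 libraries (16691 genes). Expression is given as CPM (counts scaled to library size), mean ± SD, and log CPM used a prior count of 2. The median log2 fold change of all tested genes lay between -0.0168 and 0.00923 in the 5 comparisons. Groups did not overlap for 476 (3.08%), 1420 (9.15%), 661 (4.24%), 2242 (14.5%) and 2610 (16.7%) of genes in the comparisons of 1 and 10 µM at 3 h, 1 and 10 µM at 24 h, and over time, where chance gives 2.86%.

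Gene lists, 45 written beforehand, were tested with camera of limma 3.58.1 (preset correlation between genes 0.01) and adjusted over the 42 lists with at least 5 measured members. The lists of CAR and PXR metabolism, metallothioneins and melanoblasts had fewer measured members and were not tested. With an estimated correlation, camera derives that correlation from the data.

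Genes were named by a rule: in each comparison, among called genes with a symbol, a mean of at least 50 counts in the higher group and groups that do not overlap, up to 8 that rose most and 8 that fell most, without predicted genes. Every hedgehog pathway gene, up to 4 called members of each other list and up to 2 where none was called could be named, and Sox9, Col2a1, Runx2, Sp7, Col10a1, Ihh, Shh, Ptch1 and Gli1 always. The text takes a selection from these. Ccnd1, Foxf2 and Mbnl3 were named after their values were seen. Genes named for dose differences and for changes between times were selected from the same lists after their values were seen.

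Whether replicate numbers pair the libraries was tested by correlating residuals of libraries with the same number across groups, with a bound of 0.1. The correlations were 0.11 to 0.355 and 0.106 to 0.279 for 1 and 10 µM at 3 h, and 0.153 to 0.343 and 0.14 to 0.361 at 24 h, over the bound in all 4 pairs. The correlation with the own number was the highest for 3 and 1 of 4 replicate numbers at 3 h and for 4 and 3 of 4 at 24 h, so for 10 µM at 3 h the split between replicates 1 and 2 and replicates 3 and 4 is not separated from a pairing by number. For control over time they were 0.0854 to 0.345, over the bound in 3 of 4 pairs. Replicate number as a block was therefore given beside the test for the comparisons with control. Alternatives tried were RLE scaling, DESeq2 1.42.0, no filter on low counts, a mean of at least 50 counts, the replicate block, all 24 libraries in 1 fit, each library left out in turn, a fold of at least 1.5, and an adjusted p under 0.01. For lists, an estimated correlation and the fry test were tried. Added after the data were seen were a term for replicates 1 and 2 against 3 and 4, fits within each of these pairs of replicates, removal of each library's trend with gene length and GC content (for genes and for lists), and removal of Yam1 or of the 2 libraries rich in it. Settings foreseen for normalized values (pseudocounts and filters) and for tables without values per library do not apply, since raw counts were deposited. Overlaps of calls were compared with 10 simulations of unchanged groups that share their controls.

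The test was run on simulated data in which 200 genes were changed. The changed genes were drawn from those with a mean of at least 50 counts. The simulated counts did not hold the split between replicates 1 and 2 and replicates 3 and 4. Genes changed by a factor of 1.5, 2 and 4 were recovered in 62.7, 88.1 and 98.5% of cases for 1 µM at 3 h, and in 67.2, 89.6 and 93.9% for 10 µM at 3 h. The shares were 34.3, 85.1 and 98.5% for 1 µM at 24 h and for control over time, and 43.3, 83.6 and 97% for 10 µM at 24 h. Unchanged genes were called too: 16 of 182 calls for 1 µM and 12 of 179 for 10 µM at 3 h. They were 8 of 153 for 1 µM and 6 of 155 for 10 µM at 24 h, and 11 of 156 over time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.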

Results

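Gene expression was measured by poly-A RNA sequencing in forelimb buds taken from CD1 mouse embryos at gestation day 13. The limb buds were grown in culture for 3 or 24 h with the solvent DMSO (control), or with 1 or 10 µM tert-butylphenyl diphenyl phosphate (BPDP). BPDP is an organophosphate ester used as a flame retardant and plasticizer. The series title places the question in hedgehog signalling, the pathway through which Sonic and Indian hedgehog proteins direct limb patterning and cartilage growth. There were 6 groups of 4 libraries, 24 in all. Total counts per library ranged from 14165947 (10 µM at 3 h, replicate 3) to 20823058 (1 µM at 3 h, replicate 3), over 25844 genes. Nothing in the labels says that replicates came from separate litters or cultures, so the p-values measure the spread between these samples. Xist was near 0 in 4 libraries (0.405 and 0.379 CPM in 3 h controls 1 and 2, 0.31 CPM in 1 µM at 24 h replicate 3, and 0 CPM in 10 µM at 24 h replicate 3). The remaining libraries carried between 117.4 and 707.0 CPM of Xist. At 3 h the libraries with 10 µM had 176.2 to 607.7 CPM, and controls 3 and 4 had 325.9 and 250 CPM. The list of sex-linked genes was called in none of the 5 comparisons. It joins Xist with Y-linked genes, which would move in opposite directions, so this does not show that the sexes were balanced between groups.

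Between 3 and 24 h of culture without BPDP, 17 of 22 cartilage genes and 20 of 26 muscle genes rose, and all 22 G2/M genes, which serve cell division, fell. These lists had an adjusted p = 0.201, 0.201 and 0.114 with an estimated correlation. Col2a1, the main collagen of cartilage, rose from 2720 ± 410 to 5539 ± 1296 CPM (mean ± SD, n = 4; log2 fold change 1.03, SE 0.19, adjusted p = 0.0043). Acta1, skeletal muscle actin, rose from 218 ± 35.5 to 602 ± 94.1 CPM (1.47, SE 0.143, adjusted p = 0.00011). Mki67, a marker of cycling cells, fell from 255 ± 12.2 to 148 ± 6.45 CPM (log2 fold change -0.78, adjusted p = 0.000157). In all 1494 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 852 higher and 642 lower at 24 h, of 15640 tested. Of these, 300 were higher and 74 were lower by a factor of at least 2.

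Of 22 measured cartilage genes, 17 rose and none fell (18 when adjusted over the list alone; median log2 fold change 1.02). They included Col9a2 (0.94), which codes for a collagen IX chain, Chad (1.46), which codes for chondroadherin, and Susd5 (1.21). The list was called by camera with an adjusted p of 1.9e-12, and had an adjusted p = 0.201 with an estimated correlation. Of 12 genes of hypertrophic chondrocytes 5 rose (11 over the list alone), among them Mef2c (0.93), a transcription factor of chondrocyte hypertrophy, and Alpl (1.37), the alkaline phosphatase of mineralizing tissue. Col10a1, the collagen of hypertrophic cartilage, did not pass (3.32, SE 1.02, adjusted p = 0.108), with 79.9 ± 71.5 CPM at 24 h against 8.01 ± 5.76 CPM at 3 h. Of 15 osteoblast genes 4 rose and 1 fell. Runx2, a regulator of bone and hypertrophic cartilage, rose by 0.62 (adjusted p = 0.011) and Sp7, a regulator of osteoblasts, by 0.72 (adjusted p = 0.0422), though Sp7 lost its call without 1 library in 6 of 8 cases, with adjusted p-values up to 0.137. Sox9, the regulator of early cartilage, did not pass (-0.17, adjusted p = 0.442). Among 26 muscle genes 20 rose and none fell (22 over the list alone; median 0.97), with Myh8 at 1.30 and Tnnt3 at 1.25. With an estimated correlation, the hypertrophic and muscle lists each had an adjusted p = 0.201, and the osteoblast list an adjusted p = 0.297.

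Of 9 hedgehog target genes 4 rose over culture time and none fell (5 over the list alone, median 0.48, adjusted p = 0.00135, and 0.201 with an estimated correlation). Ptch1, which codes for a hedgehog receptor and is itself switched on by the pathway, rose by 0.86 (adjusted p = 0.019). Gli1, a transcription factor and target of the pathway, rose from 59.9 ± 10.4 to 106 ± 15.9 CPM (0.82, SE 0.134, adjusted p = 0.00221), but had an adjusted p = 0.139 when all 24 libraries shared 1 estimate of spread (2.27e-06 to 0.139 over all settings). Ptch1 lost its call without 1 library in 4 of 8 cases, with adjusted p-values up to 0.0696. Ihh, the hedgehog ligand of cartilage, had a log2 fold change of 0.46 and did not pass (adjusted p = 0.0608). All 22 G2/M genes fell (median -0.83) and 13 of 16 G1/S genes fell (15 over the list alone; median -0.52), with adjusted p-values of 0.114 and 0.201 with an estimated correlation.

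Other cell types and pathways also moved in the control cultures. Macrophage genes rose (10 of 16; median 0.88; adjusted p = 0.201 with an estimated correlation), led by Lyz2, which codes for lysozyme (2.67, 5.0 ± 1.06 to 31.9 ± 4.40 CPM), and Cd68 (1.44). Cholesterol biosynthesis genes rose (15 of 25, 19 over the list alone; median 0.59; adjusted p = 0.217 with an estimated correlation), among them Lss (1.03) and Fdps (1.01). Of 18 epidermal genes 8 rose (median 0.70, adjusted p = 0.305 with an estimated correlation), with Krt17 at 2.02. Krt77, a keratin of differentiated epidermis, had the largest rise among the named genes (7.97, SE 1.68), resting on 77.4 ± 107 CPM at 24 h. It lost its call without 1 library in 5 of 8 cases, with adjusted p-values up to 0.122. Of 32 limb patterning genes 7 fell (13 over the list alone, median -0.31, adjusted p = 0.201 with an estimated correlation), among them Lhx9 (-0.84) and Shox2 (-0.44). Genes of the integrated stress response, which many cells switch on when amino acids run short, fell (9 of 16, with 1 higher; median -0.53; adjusted p = 0.114 with an estimated correlation), with Chac1 at -1.36 and Mthfd2 at -1.02. Of 11 erythroid genes 3 fell (8 over the list alone, median -1.04, adjusted p = 0.201 with an estimated correlation). Of 14 endothelial genes 2 fell (7 over the list alone; median -0.22; adjusted p = 0.297 with an estimated correlation). A further 8 lists were called higher: FGF and MAPK feedback (median 0.31, adjusted p = 0.00158), LXR targets (0.50, 0.000856), fatty acid synthesis (0.41, 0.000117), circadian clock (0.54, 0.00135), interferon response (0.61, 0.00768), inflammatory cytokines (0.55, 0.0431), Notch (0.20, 0.0188) and matrix proteases (0.29, 0.0302). With an estimated correlation the LXR and fatty acid lists had an adjusted p = 0.201, the FGF list 0.296, the circadian list 0.318 and the other 4 lists 0.297. The calls of the inflammatory, protease and interferon lists were lost without 1 library in 3, 2 and 1 of 8 cases, with adjusted p-values up to 0.086, 0.0618 and 0.0672.

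Among single genes, Aplnr, the receptor for apelin, fell from 67.8 ± 4.22 to 8.30 ± 2.01 CPM (-3.03, SE 0.162, adjusted p = 7.28e-07), and Plvap, a protein of vessel walls, had a log2 fold change of -2.05. The count of genes was 44 within replicates 1 and 2 and 1216 within replicates 3 and 4. The count of 1494 was 791 without control replicate 3 at 3 h and 834 without control replicate 4 at 3 h.

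At 24 h with 10 µM BPDP, 5 of 8 hedgehog targets fell, 1 rose, and the transcript of the ligand Ihh rose. The target list had an adjusted p = 0.106 with an estimated correlation. Gli1 fell from 105 ± 15.3 to 1.70 ± 1.19 CPM (log2 fold change -5.89, SE 0.489, adjusted p = 0.000982, n = 4 per group). Ptch1 fell from 80.4 ± 12.8 to 22.1 ± 1.56 CPM (-1.86, SE 0.119, adjusted p = 6.08e-06). Ihh rose from 36.3 ± 7.16 to 131 ± 17.3 CPM (1.85, SE 0.141, adjusted p = 5.68e-05). In the same cultures all 22 G2/M genes, all 16 G1/S genes and 8 of 16 macrophage genes fell, and 11 of 16 genes of the integrated stress response rose. These lists had an adjusted p = 0.0535, 0.151, 0.245 and 0.223 with an estimated correlation. In edgeR's quasi-likelihood test 963 of 15508 genes passed, 430 higher and 533 lower, of which 58 and 160 differed by a factor of at least 2.

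Of 22 hedgehog pathway genes, 5 fell and 4 rose. Besides Gli1 and Ptch1, those that fell included Hhip (-2.14, SE 0.334, adjusted p = 0.00437), which codes for a membrane protein that binds hedgehog ligands and limits the pathway, and Pthlh (-1.47, adjusted p = 0.0011), which codes for parathyroid hormone-related protein. Besides Ihh, those that rose were the co-receptor genes Cdon (0.64, adjusted p = 0.00319) and Gas1 (0.45, adjusted p = 0.0384) and the gene of the secreted protein Scube3 (0.60, adjusted p = 0.0102). Gas1 lost its call without 1 library in 6 of 8 cases, with adjusted p-values up to 0.109. Smo, the signal transducer of the pathway, had a log2 fold change of -0.04 (adjusted p = 0.842), and the transcription factor genes Gli2 and Gli3 had -0.04 (adjusted p = 0.878) and 0.42 (adjusted p = 0.0846). With the replicate number as a block, Gli3 had an adjusted p = 0.00875, and over all settings 0.00843 to 0.577. Shh was below the count filter. The whole pathway list was not called (median 0.04, mean -0.48; adjusted p = 0.894). Of the 8 listed target genes 5 fell and 1, Foxf2, rose (0.46, adjusted p = 0.0388, named after its values were seen), which lost its call without 1 library in 7 of 8 cases, with adjusted p-values up to 0.12. The target list had a median of -1.67 and an adjusted p of 0.000144, or adjusted p = 0.106 with an estimated correlation. Gli1 lies on chromosome 10 (mm10, 127329889 to 127341589, minus strand), Ptch1 on chromosome 13 (63511533 to 63565520, minus strand) and Ihh on chromosome 1 (74945315 to 74951672, minus strand). The values are counts over whole genes, so they carry no information on single exons.

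**Figure D1:**
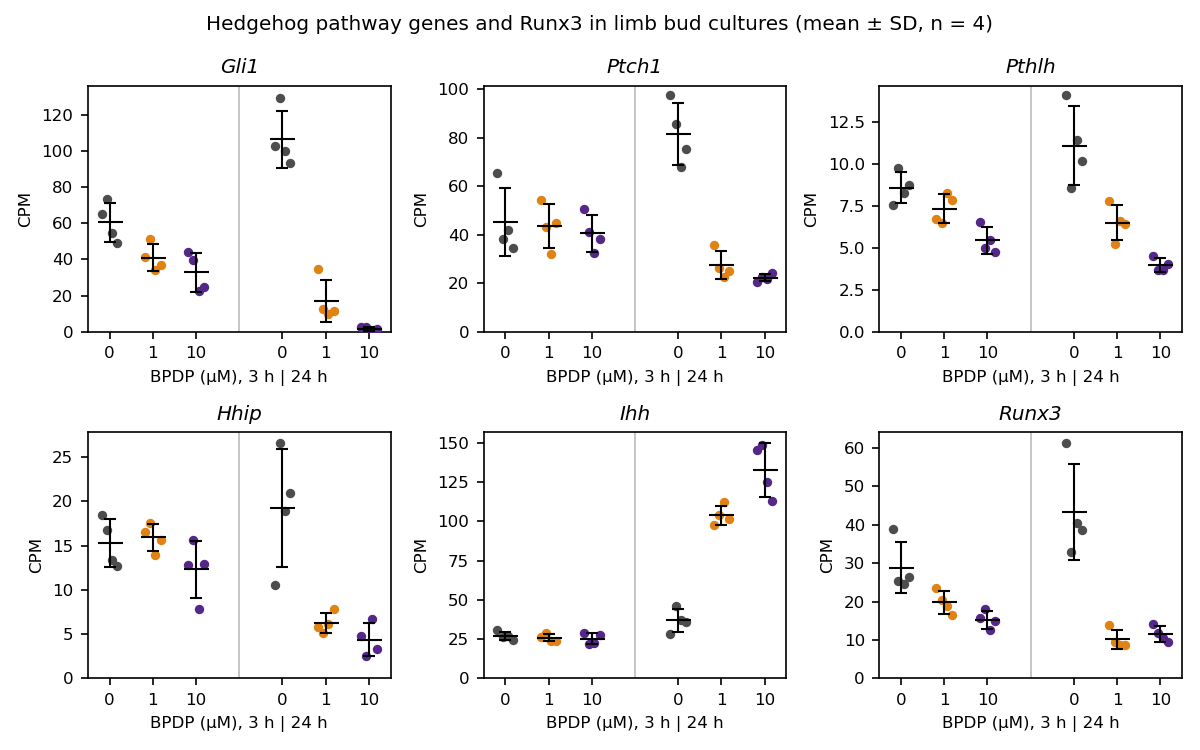
Expression in CPM (1 TMM scaling over all 24 libraries) of Gli1, Ptch1, Pthlh, Hhip, Ihh and Runx3 against BPDP concentration in µM, at 3 h (left of the grey line) and 24 h (right), with 1 point per library and bars for mean ± SD (n = 4). At 24 h all 8 treated libraries lie below the 4 controls for Gli1, Ptch1, Pthlh, Hhip and Runx3, and above them for Ihh.

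All 22 G2/M genes and all 16 G1/S genes fell with 10 µM at 24 h (medians -0.82 and -0.74). Mki67 fell from 146 ± 6.17 to 79.8 ± 3.34 CPM, and Top2a, a topoisomerase of dividing cells, from 184 ± 10.5 to 96.2 ± 12 CPM. Plk1, a mitotic kinase, had a log2 fold change of -1.03. The replication genes Mcm7 (-0.77) and Rrm2 (-1.10) also fell. The adjusted p-values of the lists were 8.29e-27 and 1.1e-17, or adjusted p = 0.0535 and 0.151 with an estimated correlation. Macrophage genes fell in 8 of 16 cases (9 over the list alone; median -1.30; adjusted p = 6.48e-10, or 0.245 with an estimated correlation). C1qa, a complement gene of macrophages, fell from 29.2 ± 7.85 to 4.90 ± 1.38 CPM (-2.57, SE 0.228), Csf1r, the receptor macrophages need for survival, from 27.1 ± 5.63 to 7.32 ± 2.02 CPM (-1.88), and Cx3cr1 by -2.78. Of 14 endothelial genes 5 fell (8 over the list alone; median -0.50; adjusted p = 8.19e-06, or 0.245 with an estimated correlation), among them Cdh5 (-0.77) and Kdr (-0.56). The erythroid list was not called (0 of 9 passed; median -0.00404; adjusted p = 0.762).

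Of 16 genes of the integrated stress response 11 rose and none fell (12 over the list alone; median 1.00; adjusted p = 7.81e-10, or 0.223 with an estimated correlation). Trib3, a pseudokinase induced by this response, rose from 14.3 ± 5.07 to 72.3 ± 27.2 CPM (2.34, adjusted p = 0.0079). Chac1, which degrades glutathione, rose from 9.78 ± 1.10 to 37.0 ± 10.8 CPM (1.92, adjusted p = 0.000366), and the folate enzyme gene Mthfd2 by 1.04. The list of the unfolded protein response of the endoplasmic reticulum was not called (1 of 15 rose; median -0.02; adjusted p = 0.558). Cholesterol biosynthesis genes rose in 9 of 25 cases (17 over the list alone; median 0.37; adjusted p = 6.26e-08, or 0.599 with an estimated correlation), with Insig1 at 0.70 and Msmo1 at 0.65.

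Of 23 cartilage genes 3 rose (median 0.33; adjusted p = 9.91e-05, or 0.721 with an estimated correlation): Susd5 (0.68), Fgfr3 (0.48) and Sox6 (0.36). Fgfr3 and Sox6 lost their calls without 1 library in 5 and 6 of 8 cases, with adjusted p-values up to 0.0819 and 0.126. Sox9 (0.28, adjusted p = 0.217) and Col2a1 (0.43, adjusted p = 0.208) did not pass, while Col2a1 had an adjusted p = 0.0401 with the replicate number as a block (0.0344 to 0.764 over all settings). Among 14 hypertrophic genes 3 rose and 2 fell (median 0.20; adjusted p = 0.286). Runx3, a partner of Runx2 in chondrocyte maturation, fell from 42.7 ± 12.4 to 11.4 ± 2.04 CPM (-1.90, adjusted p = 0.000341), and Runx2 from 50.9 ± 6.54 to 28.7 ± 5.92 CPM (-0.83, adjusted p = 0.00586). Pth1r, the receptor for parathyroid hormone-related protein, rose by 0.59 (adjusted p = 0.00175). Col10a1 (0.32, SE 0.937, adjusted p = 0.902) and Sp7 (-0.69, adjusted p = 0.136) did not pass, while Sp7 had an adjusted p = 0.0149 with the block (0.0149 to 0.643 over all settings). Joint genes went both ways (5 of 13 rose, 1 fell; median -0.02, mean 0.18; adjusted p = 0.216), with Wnt16 at 1.51 and Sfrp2 at 0.83. Of 14 Notch pathway genes 3 fell: Dll4 (-0.89), Nrarp (-1.85) and Hes1 (-0.56). The list had an adjusted p of 0.00104, or 0.245 with an estimated correlation, and each of the 3 lost its call without 1 library in at least 3 of 8 cases, with adjusted p-values up to 0.0655, 0.0714 and 0.108.

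Further lists were called with few or no single genes past the threshold. Of 18 epidermal genes 2 fell (6 over the list alone; median -0.81; adjusted p = 7.98e-05, or 0.721 with an estimated correlation), Grhl3 (-1.55) and Krt5 (-1.26). Krt5 lost its call without 1 library in 2 of 8 cases, with adjusted p-values up to 0.056. Of 14 matrix protease genes 2 rose (4 over the list alone; median 0.22; adjusted p = 0.00514, or 0.63 with an estimated correlation), with Timp2 at 0.52. No hypoxia and glycolysis gene of 25 passed (median -0.68; adjusted p = 0.0296, or 0.82 with an estimated correlation), and that call was lost without 1 library in 4 of 8 cases, with adjusted p-values up to 0.862, with a term for replicates 1 and 2 against 3 and 4 (adjusted p = 0.0589), and with length and GC trends removed (adjusted p = 0.0596). With those trends removed the ribosomal protein list was called (adjusted p = 0.0239, against 0.29 without the removal, or adjusted p = 0.866 with an estimated correlation). By size of change the named genes also included Adcyap1 (3.06, SE 0.386), which codes for a neuropeptide, and Hrk (2.17, SE 0.306), which codes for a protein that promotes cell death, both higher. Ambn (-5.24, SE 0.864) and Clic6 (-3.41, SE 0.432), a chloride channel gene, were lower.

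With the replicate number as a block, 1645 genes passed at 10 µM and 24 h, 771 higher and 874 lower, and 958 of the 963 genes were among them. Within replicates 1 and 2 the count was 6 and within replicates 3 and 4 it was 953, and all 963 genes went the same way in both. Since these genes were called from the same libraries, this agreement is largely built in and is no separate support. Without 10 µM replicates 4, 1, 3 or 2 the count was 491, 504, 555 or 562, and it was 624 without control replicate 4. The authors' deposited table lists 1460 genes with an adjusted p under 0.05 for this comparison, 680 higher and 780 lower, and 959 of the 963 genes are among them.

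**Figure D2:**
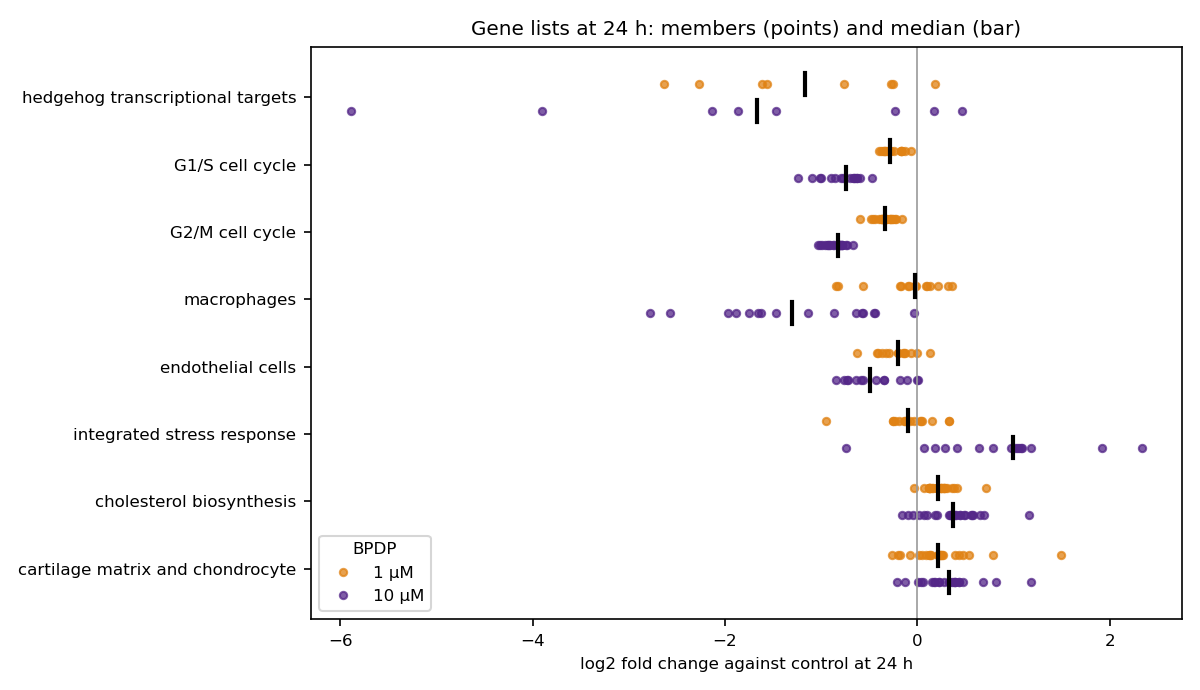
Log2 fold change against control at 24 h for the members of 8 gene lists (points) and their median (black bar), at 1 µM (orange) and 10 µM (purple). At 10 µM all G1/S and G2/M members lie below 0, and Gli1 (-5.89) is the lowest hedgehog target.

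At 24 h with 1 µM, 12 of 15578 genes passed, 3 higher and 9 lower, with the hedgehog pathway genes Ptch1, Hhip and Ihh among them. Ptch1 fell from 81.2 ± 13.2 to 27.4 ± 5.75 CPM (-1.57, SE 0.154, adjusted p = 0.000657), and Hhip from 19.1 ± 6.59 to 6.21 ± 1.14 CPM (-1.62, adjusted p = 0.0268). Ihh rose from 36.7 ± 7.32 to 103 ± 6.20 CPM (1.49, SE 0.131, adjusted p = 0.000447). Runx3 fell from 43.1 ± 12.6 to 10.2 ± 2.43 CPM (-2.08, adjusted p = 0.00119). Pcsk6, which codes for a proprotein convertase that activates secreted growth factors, rose by 1.04 and Cytl1, a secreted protein of cartilage, by 0.99. Bcl2, an inhibitor of cell death (-1.04), Foxc2, a transcription factor of mesenchyme (-1.04), Batf3 (-2.02), Clic6 (-1.89) and Ccnd1, which codes for cyclin D1 (-0.83, named after its values were seen), also fell.

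Gli1 did not pass at 1 µM and 24 h (-2.64, SE 0.441, adjusted p = 0.245). Replicate 1 had 34.7 CPM and the other replicates 9.62 to 12.8 CPM, against 106 ± 15.9 CPM in the controls. Without 1 µM replicate 1, Gli1 had a log2 fold change of -3.24 and an adjusted p = 2.39e-06, and it did not pass without any other library (adjusted p-values up to 0.77). All 4 treated libraries were below all 4 controls, and with the replicate number as a block Gli1 had an adjusted p = 0.0342 (9.19e-07 to 0.77 over all settings). Runx2 (-0.76, adjusted p = 0.0848) passed with the block (adjusted p = 0.0352; 0.000486 to 0.51 over all settings) and Ccnd1 did not (adjusted p = 0.0684; 3.43e-06 to 0.636). Shh had 1.23 ± 0.508 CPM against 0.218 ± 0.064 CPM (2.47, SE 0.497, adjusted p = 0.151), a level of few reads. Sox9 (0.26), Col2a1 (0.13), Col10a1 (0.77) and Sp7 (-0.61) did not pass, with adjusted p-values of 0.882, 0.974, 0.97 and 0.719. Of 23 hedgehog pathway genes 1 rose and 3 fell (3 and 5 over the list alone), and the list was not called (median 0.02, mean -0.15; adjusted p = 0.824).

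Of 8 hedgehog targets 3 fell (5 over the list alone; median -1.16; adjusted p = 1.71e-09, or 0.0638 with an estimated correlation). No G2/M gene passed over all genes, but 17 of 22 were lower when adjusted over the list alone (median -0.34; adjusted p = 8.32e-19, or 0.139 with an estimated correlation). The G1/S list was also lower (0 of 16 passed, 1 over the list alone; median -0.28; adjusted p = 4.48e-08, or 0.477 with an estimated correlation). Without single genes past the threshold, 3 lists were called lower: Notch (median -0.23, adjusted p = 0.00189), endothelial (-0.20, 0.000598), and hypoxia and glycolysis (-0.62, 0.000681). Another 4 were called higher: cholesterol biosynthesis (0.21, 2.15e-08), cartilage (0.22, 0.000266), muscle (0.15, 0.000868) and aryl hydrocarbon receptor (0.50, 0.0378). With an estimated correlation none of these was called, with adjusted p = 0.477 for the Notch, endothelial and aryl hydrocarbon receptor lists, 0.933 for hypoxia and muscle, 0.718 for cholesterol and 0.849 for cartilage. The calls of the aryl hydrocarbon receptor, muscle, cartilage and hypoxia lists were lost without 1 library in 4, 2, 1 and 1 of 8 cases, with adjusted p-values up to 0.175, 0.17, 0.0621 and 0.784, and that of the aryl hydrocarbon receptor list also with length and GC trends removed (adjusted p = 0.0648). The macrophage list (median -0.02, adjusted p = 0.905) and the integrated stress response list (median -0.10, adjusted p = 0.567) were not called. DESeq2 called 59 genes, and the authors' deposited table lists 55 with an adjusted p under 0.05, 21 higher and 34 lower. The count was 0 within replicates 1 and 2 and 29 within replicates 3 and 4, with all 12 genes going the same way in both, as calls from these libraries largely must. Without 1 µM replicate 4 or control replicate 4 it was 7. Hhip, Clic6, Batf3, Ccnd1, Foxc2 and Bcl2 each lost their call without 1 library, in 7, 6, 6, 5, 4 and 3 of 8 cases, with adjusted p-values up to 0.168, 0.182, 0.101, 0.143, 0.0803 and 0.0715.

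The doses were compared directly at 24 h in 1 fit of all 24 libraries, where 559 of 16691 genes differed, 203 higher and 356 lower with 10 than with 1 µM. Gli1 (-3.26, SE 0.488, adjusted p = 0.0007) was lower with 10 µM. Ptch1 (-0.30, SE 0.193), Hhip (-0.53, SE 0.272), Ihh (0.36, SE 0.115) and Runx3 (0.17, SE 0.196) did not pass, with adjusted p-values of 0.472, 0.341, 0.0855 and 0.744. Among macrophage genes C1qa (-2.48, adjusted p = 6.92e-08) and Csf1r (-1.70, adjusted p = 5.15e-06) were lower with 10 than with 1 µM, and among stress response genes Slc3a2, an amino acid transporter subunit (1.26, adjusted p = 1.41e-06), and Trib3 (2.37, adjusted p = 3.19e-05) were higher. Plk1 was lower (-0.78). The 12 genes called at 1 µM were all called at 10 µM in the same direction, 3 higher and 9 lower, where independent calls would share 0.0836 and 0.313. The 10 simulations of unchanged groups against the same controls shared no gene, but had at most 3 and 4 calls to share. Split so that each dose had 2 control libraries of its own, 5 of 5, 8 of 9, 5 of 5 and 8 of 8 calls were shared. Fold changes at the 2 doses correlated across genes at 0.582 with a covariance of 0.0746. The simulations gave 0.498 and 0.0415, and split controls gave correlations of -0.0288 to 0.255. The count of 559 was 275 without 1 µM replicate 1, 322 without 1 µM replicate 3, 327 without 10 µM replicate 1 and 370 without 10 µM replicate 3.

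At 3 h, 10 µM BPDP lowered Dhrs3, which codes for a retinaldehyde reductase that limits retinoic acid and is itself induced by it. Dhrs3 fell from 81.1 ± 8.20 to 38.6 ± 3.16 CPM (-1.07, SE 0.092, adjusted p = 0.000183), and was the 1 gene of 15520 that passed in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 2411 genes, 1363 higher and 1048 lower, where chance gives 776. The retinoic acid list was lower as a whole (1 of 15 passed, 9 over the list alone; median -0.30; adjusted p = 3.44e-07, or 0.232 with an estimated correlation). Cyp1b1, a target of the aryl hydrocarbon receptor (-1.39), Runx3 (-0.91) and Wnt4 (-0.60) did not pass (each adjusted p = 0.067), but passed with the replicate number as a block, with adjusted p-values of 0.00982, 0.00982 and 0.0448 (9.45e-09 to 0.185, 0.000108 to 0.583 and 0.000717 to 0.769 over all settings). Gli1 had 33.7 ± 11 CPM against 61.8 ± 11 CPM (-0.87, SE 0.23, adjusted p = 0.143, 0.0072 with the block, and 0.000659 to 0.353 over all settings). Ptch1 (-0.14, SE 0.207, adjusted p = 0.784), Ihh (-0.09, adjusted p = 0.753), Runx2 (-0.32, adjusted p = 0.392), Sp7 (-0.23, adjusted p = 0.555), Sox9 (0.03, adjusted p = 0.92), Col2a1 (-0.13, adjusted p = 0.738) and Col10a1 (-0.19, adjusted p = 0.935) did not pass.

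A further 9 lists were called lower at 3 h with 10 µM. They were ribosomal proteins (median -0.28, adjusted p = 1.73e-05), immediate early genes (-0.18, 3.33e-05), hedgehog targets (-0.30, 0.00236), hypoxia and glycolysis (-0.17, 0.00715), aryl hydrocarbon receptor (-0.59, 0.0105), G1/S (-0.12, 0.011), joint (-0.10, 0.0181), NRF2 oxidative stress (-0.15, 0.0187) and tendon (-0.18, 0.0384). With an estimated correlation none was called, with adjusted p-values between 0.361 and 0.626. Adjusted over each list alone, 4 of 9 hedgehog targets, 6 of 25 immediate early genes, 4 of 6 aryl hydrocarbon receptor genes, 3 of 10 tendon genes and 2 of 13 joint genes were lower. The calls of the tendon, NRF2, joint, G1/S and hypoxia lists were lost without 1 library in 4, 2, 1, 1 and 1 of 8 cases, with adjusted p-values up to 0.215, 0.108, 0.0565, 0.0515 and 0.0669. The integrated stress response list was not called (median 0.14, adjusted p = 0.074; 5 of 16 higher over the list alone). Once each library's trend with gene length and GC content was removed, a setting chosen after the data were seen, 9 lists were called. The joint (adjusted p = 0.103) and NRF2 (adjusted p = 0.0705) lists lost their calls, the other 8 lists were called lower, and the integrated stress response list was called higher (adjusted p = 0.000348). Without the removal that list had an adjusted p = 0.564 with an estimated correlation.

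The count at 3 h with 10 µM depended on the model. The block gave 335 genes, 244 higher and 91 lower, though 1 of 4 replicate numbers correlated most with its own number here. A term for replicates 1 and 2 against 3 and 4 gave 446. DESeq2 gave 486, all 24 libraries in 1 fit 52, and no filter on low counts 142, and the authors' deposited table lists 446, 309 higher and 137 lower. It was 4 within replicates 1 and 2 and 48 within replicates 3 and 4, and it was 11 without control replicate 1 and 2 without 10 µM replicate 3. Fold changes rose with gene length across genes (Spearman correlation 0.417, and -0.245 with GC content; genes are not independent replicates). The genes higher with the block had a median length of 6909.5 bases, those lower 1873 bases, and all tested genes 3057.5 bases. With each library's trend with length and GC content removed and the block kept, 25 genes passed, Dhrs3, Gli1, Cyp1b1 and Runx3 among them.

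**Figure D3:**
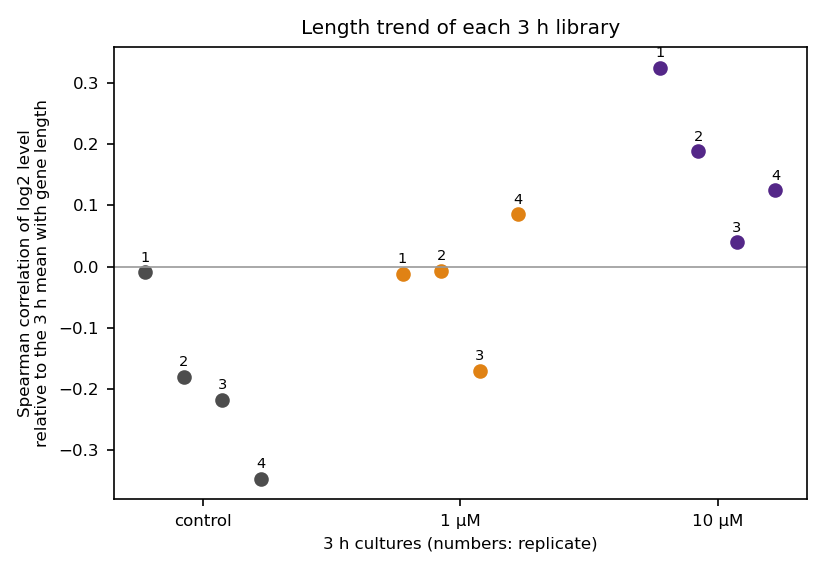
Spearman correlation across genes between gene length and the log2 level of each 3 h library relative to the 3 h mean, by treatment, with the replicate number at each point. The 4 controls lie between -0.346 and -0.00911 and the 4 libraries with 10 µM between 0.0398 and 0.325.

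At 3 h with 1 µM no gene passed in edgeR's test (0 of 15446; 801 at an unadjusted p under 0.05, 482 higher and 319 lower, where chance gives 772; 0 by DESeq2 and 0 in the authors' deposited table). With the block 2 genes passed: Gli1 (-0.57, adjusted p = 0.0065) and Mbnl3, a splicing regulator named after its values were seen (0.64, adjusted p = 0.042). Over all settings their adjusted p-values ran from 0.0027 to 1 and from 0.0406 to 1. Gli1 had 40.5 CPM against 59.9 CPM in the controls, and an adjusted p = 0.928 without the block. Dhrs3 (-0.36), Runx2 (-0.28), Sp7 (-0.31), Sox9 (0.12), Col10a1 (-0.71), Col2a1 (-0.13), Ihh (-0.07) and Ptch1 (-0.05) did not pass, with adjusted p-values of 0.928, 0.947, 0.947, 0.963, 0.963, 0.963, 0.988 and 0.997. Cholesterol biosynthesis genes were called higher (median 0.10, adjusted p = 0.00411), and hedgehog targets (-0.14), retinoic acid genes (-0.10) and immediate early genes (-0.10) lower, each with an adjusted p of 0.032. None was called with an estimated correlation (adjusted p = 0.982 for all 4). Fold changes rose with gene length (Spearman correlation 0.258) and fell with GC content (-0.314) across genes, and with the trends of length and GC content removed the hedgehog target (adjusted p = 0.0754), retinoic acid and immediate early lists (each adjusted p = 0.506) lost their calls, while the cholesterol list kept its call (adjusted p = 0.000201) and the macrophage list was called higher (adjusted p = 0.0204). Without the removal the macrophage list had an adjusted p = 0.982 with an estimated correlation. Adjusted over the list alone, 1 of 25 cholesterol genes was higher, and 2 of 8 hedgehog targets and 1 of 15 retinoic acid genes were lower. The calls were lost without 1 library in 2, 4, 6 and 4 of 8 cases, with adjusted p-values up to 0.171, 0.364, 0.136 and 0.364. Within replicates 1 and 2 the count was 1, within replicates 3 and 4 it was 2, and it was 1 without control replicate 1. In the simulated data at this depth 88.1% of genes changed by a factor of 2 were found. Those genes had a mean of at least 50 counts, and the replicate split was not simulated. The share therefore does not show that changes of this size were absent here.

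Between the doses at 3 h no gene of 16691 differed in the fit of all libraries (smallest adjusted p = 0.0591; 1385 at an unadjusted p under 0.05, where chance gives 835; 4 by DESeq2). With the block 3 genes passed, among them Dhrs3 (-0.72, adjusted p = 0.0206) and Cyp1b1 (-1.30, adjusted p = 0.0206), with 0.000719 to 0.615 and 8.42e-05 to 1 over all settings. Fold changes of both doses at 3 h correlated at 0.475 across genes, with a covariance of 0.0293, against 0.513 and 0.0309 in the simulations, and at -0.145 to 0.153 with split controls.

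The response to 10 µM changed between 3 and 24 h for 432 genes, 164 in the positive and 268 in the negative direction, by a test of the interaction. The change was 1.94 for Ihh (adjusted p = 8.51e-08), -5.02 for Gli1 (adjusted p = 0.000101), -1.72 for Ptch1 (adjusted p = 0.000484), -1.02 for Mki67 (adjusted p = 1.57e-05), -2.27 for C1qa (adjusted p = 3.56e-05) and 2.08 for Trib3 (adjusted p = 0.00222). Dhrs3, lower at both times, had a change of 0.26 that did not pass (SE 0.175, adjusted p = 0.554). For 1 µM there were 575 genes at an unadjusted p under 0.05, fewer than the 835 that chance gives. The response of 6 genes changed: Ihh (1.56, adjusted p = 1.03e-05), Pcsk6 (1.05, adjusted p = 0.017), Bcl2 (-1.05, adjusted p = 0.00156), Runx3 (-1.54, adjusted p = 0.0188), Ptch1 (-1.52, adjusted p = 0.0304) and Sms, which codes for spermine synthase (-0.65, adjusted p = 0.0372). Ptch1, Sms, Runx3 and Pcsk6 lost this call without 1 library in 12, 11, 8 and 2 of 16 cases, with adjusted p-values up to 0.13, 0.154, 0.0877 and 0.0551, and the count ranged from 3 to 10. It was 3 without control replicates 2, 3 or 4 at 3 h, control replicate 4 at 24 h, 1 µM replicates 1 or 2 at 3 h, or 1 µM replicates 2, 3 or 4 at 24 h, and 10 without 1 µM replicate 1 at 24 h. Fold changes at 3 and 24 h correlated across genes at 0.168 for 10 µM and 0.206 for 1 µM.

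Replicates 1 and 2 of every group differed from replicates 3 and 4. After removal of group means, the first principal component held 19.5% of the variance, with 12 of 12 libraries of replicates 1 and 2 above 0 and 12 of 12 of replicates 3 and 4 below. Of 16691 genes 655 were higher and 906 lower in replicates 3 and 4. Lower there were 17 of 23 cartilage genes, 9 of 14 hypertrophic genes, 8 of 15 osteoblast genes and 7 of 10 tendon genes, and higher there were 12 of 32 limb patterning genes and 6 of 22 G2/M genes. Each group held 2 libraries of each kind.

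**Figure D4:**
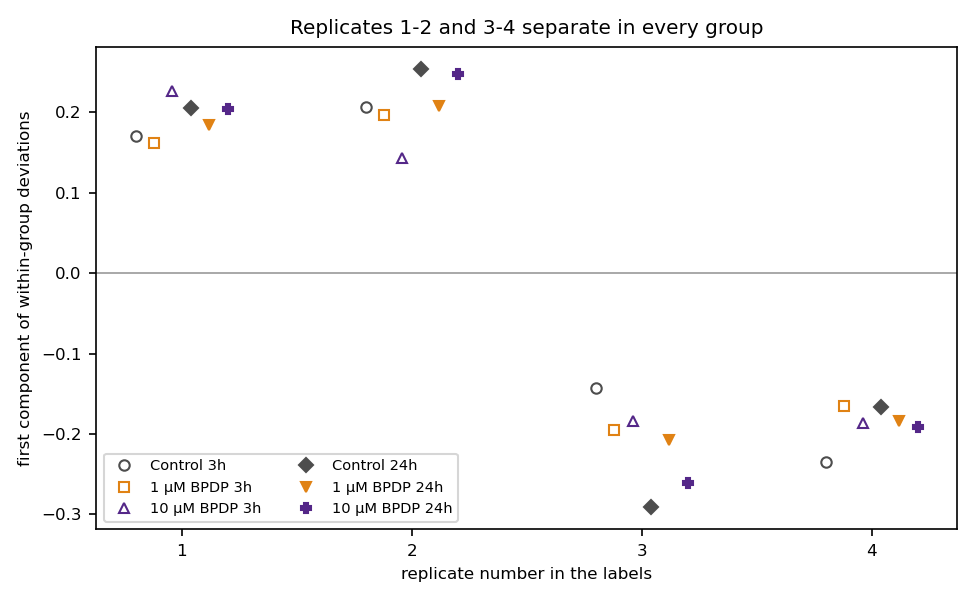
First principal component of the deviations of the 24 libraries from their group means (arbitrary units) against the replicate number in the labels, with 1 symbol per group. The 12 libraries of replicates 1 and 2 lie above 0 and the 12 of replicates 3 and 4 below.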

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

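The rules for unlike libraries and for effects that differ between times were set beforehand. Chosen after the results were seen were the tests of the replicate split for hedgehog targets, of macrophage number, vessel tissue and the replicate split for macrophage genes, of length and GC content and of depth at 3 h, the removal of Yam1, and the regrouping counts.

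In 90 groups of 4 values tested for a library far from the others, 6 stood out, where chance gives 4.5. The share of mitochondrial counts was 1.22% in 10 µM at 3 h replicate 1, against 2.13 to 2.29% in the other replicates. The share of Yam1 was 4.46% in 3 h control replicate 4 (others 0.0792 to 0.0986%) and 5.36% in 1 µM at 3 h replicate 3 (others 0.0842 to 0.129%). In the latter library the 10 most abundant genes took 11.8% of counts (others 5.94 to 6.92%). Shh had 0.0679 CPM in 10 µM at 3 h replicate 3 and 0 CPM in the others, which is a single read. Gli1 had 34.7 CPM in 1 µM at 24 h replicate 1 and 9.62 to 12.8 CPM in the others. With both libraries rich in Yam1 left out, or Yam1 removed, the count for 1 µM at 3 h stayed at 0 (edgeR; 801 genes at an unadjusted p under 0.05 with all libraries, and 0 by DESeq2).

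Effects of 10 µM differed between 3 and 24 h by the interaction test for Ihh (1.94, adjusted p = 8.51e-08), Gli1 (-5.02, adjusted p = 0.000101), Ptch1 (-1.72, adjusted p = 0.000484) and Hhip (-1.84, adjusted p = 0.00349). Effects of 1 µM differed for Ihh (1.56, adjusted p = 1.03e-05) and Ptch1 (-1.52, adjusted p = 0.0304). Ptch1 lost that call at 1 µM without 1 library in 12 of 16 cases, with adjusted p-values up to 0.13.

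The first pattern weighed is the fall of the hedgehog targets Gli1, Ptch1 and Hhip at 24 h with 10 µM. A broad loss of the cells that carry the pathway would lower its receptors and effectors too. Against this, 8 pathway genes listed neither as ligands nor as targets had a median log2 change of 0.156 (-0.151 to 0.643, interquartile range 0.469). Some of the 8, Cdon and Gas1 among them, rose. Whether these respond to the pathway themselves was not tested, and such a rise could hide a loss of cells and lift the median. The lowest of the 8 still lay at -0.151, while the least changed of Gli1, Ptch1 and Hhip had -1.86. Loss of only those cells in which the targets are high stays open. Counts of whole limb buds do not show which cells carry the 8 genes. Every group held both kinds of replicates, so the split between replicates 1 and 2 and replicates 3 and 4 does not part treated from control libraries. A fall in only 1 of these pairs of replicates is argued against: the 3 genes fell by at least 1.62 on the log2 scale in both (nearest to 0, -1.62, lowest -6.88). Lower hedgehog signalling despite more Ihh transcript may be a response to BPDP, a hypothesis found and tested on the same libraries, to which the falls at 1 µM add no separate test, since both doses share their controls. Whether the signal is changed at the ligand, the receptor or the nucleus stays open, since transcript counts do not measure it.

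The second pattern is the fall of macrophage genes at 24 h with 10 µM. All 16 members of the list with over 2 CPM in the controls were lower, as a loss of macrophages needs, but unevenly, from -2.78 to -0.0309 (median -1.31, interquartile range 1.21). Less blood in the treated limbs is argued against by the erythroid list (median -0.00404, interquartile range 0.161, where a fall as large as the rule required lies at -0.653). A fall in only 1 of the pairs of replicates is argued against by medians of -1.11 and -1.26 in them. Less vessel tissue stays open: the endothelial list fell (5 of 14 genes, median -0.498, -0.845 to 0.00869, interquartile range 0.474), and its median lies above -0.653 by less than that range. Fewer macrophages and a changed state of those left cannot be told apart: an interquartile range over 1 was first set, after the values were seen, as a bound that excludes loss, and was dropped because members that other cells also express would fall less and could give the unevenness.

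The third pattern is the rise of longer genes at 3 h with 10 µM (Spearman correlation of fold change with length 0.417). In the other comparisons it was 0.258 with 1 µM at 3 h against the same controls (0.0813 within replicates 1 and 2, 0.298 within 3 and 4), 0.162 with 1 µM at 24 h (-0.0499 and 0.31, so the sign turned within replicates 1 and 2), 0.195 with 10 µM at 24 h (0.127 and 0.2) and 0.094 over time (0.0631 and 0.106). Correlations with GC content were -0.245 here, -0.314 with 1 µM at 3 h, -0.22 and -0.101 with 1 and 10 µM at 24 h, and 0.0164 over time. Removing each library's trend with length and GC content took the calls with the replicate block from 335 to 25, so a technical bias between libraries may explain most of them. Of the 244 genes higher with the block 14 were still called (median log2 fold change 0.43 before and 0.226 after, SE 0.0827 and 0.0781), and 46 kept an unadjusted p within the range of the block calls, so most of these calls ended because the folds shrank. Of the 91 lower genes 9 were still called (-0.448 and -0.363, SE 0.0908 and 0.089), and 45 kept such a p, so many of these calls ended through the adjustment for multiple tests. The falls of Dhrs3 and Gli1 are not explained this way: both kept their calls, at -0.983 and -0.863. A trend in only 1 of the pairs of replicates is argued against by correlations of fold change with length of 0.382 within replicates 1 and 2 and 0.338 within 3 and 4. For depth, totals overlapped: 1 of the 4 treated libraries lay above the highest control (14165947 to 19800595, against 19369801). Treated replicates 3 and 4 (14165947 and 14409906) lay below the lowest control (17308913), so depth is not excluded within that pair. Treated replicates 1 and 2 (17366351 and 19800595) each lay above the control of the same number (17308913 and 17643060). The trend of 0.382 there argues against lower depth as its source within that pair. A change in the RNA of longer genes in the cells themselves stays open.

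Other groupings of the same libraries were tested. For genes with 10 µM at 24 h, 1 of 35 splits of the 8 libraries, the real one, gave as many calls (963, highest other 56), and over time likewise 1 of 35 (1494, highest other 34). The doses at 24 h also gave 1 of 35 (559, highest other 3). These counts argue against chance, but 1 of 35 is the smallest share that the splits can give. In the comparisons with control and over time, only 8 splits part all pairs of equal replicate number, and a rank among these is weaker still. For the change of the 10 µM effect (432) 4 of 100 drawn assignments, the real one included, gave as many, and the 3 others gave more (594, 605 and 606). These draws, like those for the change of the 1 µM effect, shuffled the labels within each time separately. They ask whether there is no effect at either time. They therefore cannot decide whether chance explains a change of the effect. For 1 µM at 3 h (35 of 35; 0, highest other 314) and the doses at 3 h (35 of 35; 0, highest other 2), any split gives at least the real count of 0, so these counts say nothing of chance (edgeR; 801 and 1385 genes at an unadjusted p under 0.05, and 0 and 4 by DESeq2). Chance is not excluded for 10 µM at 3 h (5 of 35; 1, highest other 173), for 1 µM at 24 h (3 of 35; 12, highest other 81) or for the change of the 1 µM effect (6 of 100; 6, highest other 34).

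Splits that call far more genes than the real one point to a structure of the libraries. At 3 h the highest counts, 314 and 173, came from the split of replicates 1 and 2 against 3 and 4, and at 24 h with 1 µM that split gave 61. The highest there, 81, came from replicates 1 and 3 against 2 and 4 of both groups, which also keeps libraries of equal number together. Among the 8 splits that part all pairs of equal replicate number, as the real one does, the highest other was 0 for 1 µM at 3 h, 1 for 10 µM at 3 h and 0 for 1 µM at 24 h. With the replicate block the real counts were 2, 335 and 16, and the highest others 20, 1 and 0. For lists chance is not excluded in any comparison: 20 of 35 splits gave as many for 1 µM at 3 h (4, highest other 19), 15 of 35 for 10 µM at 3 h (10, highest other 17), 21 of 35 for 1 µM at 24 h (10, highest other 16), 18 of 35 for 10 µM at 24 h (12, highest other 19) and 3 of 35 over time (22, highest other 25).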

How the results depend on the processing

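The replicate split term, the fits within pairs of replicates, the removal of length and GC trends for genes and for lists, and the removal of Yam1 or of both libraries rich in it were chosen after the results were seen, and the other alternatives were planned. No called result reversed its direction under any of them. Of the genes named or eligible to be named that were not called, 17 of 112 at 1 µM and 19 of 110 at 10 µM at 3 h, 22 of 107 and 9 of 45 at 24 h, 13 of 40 over time, and 1 of 5 between doses at 24 h changed sign under at least 1 setting. Counts not given here stayed within a factor of 1.5.

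For 10 µM at 24 h (963 genes) the count was 1564 with DESeq2, 1645 with the replicate block, 1582 with the block and length and GC trends removed, 1870 with all 24 libraries in 1 fit, 553 with a fold of at least 1.5, 336 at an adjusted p under 0.01, and 6 within replicates 1 and 2. Leaving out 1 library gave 491 (without 10 µM replicate 4) to 1242 (without control replicate 2). For 1 µM at 24 h (12) it was 59 with DESeq2, 95 with all libraries, 6 at an adjusted p under 0.01, 0 and 29 within replicates 1 and 2 and within 3 and 4 (edgeR; 917 at an unadjusted p under 0.05 with all 8 libraries), and 7 (without control or 1 µM replicate 4) to 12 without 1 library.

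For 10 µM at 3 h (1) the count was 486 with DESeq2, 142 without a filter, 335 with the replicate block, 446 with the replicate split term, 25 with the block and trends removed, 52 with all libraries, 4 and 48 within the pairs of replicates, and 1 to 11 without 1 library (11 without control replicate 1). For 1 µM at 3 h (0 by edgeR and DESeq2; 801 at an unadjusted p under 0.05) it was 2 with the block, 7 with the block and trends removed, 1 and 2 within the pairs of replicates, and 0 to 1 without 1 library (1 without control replicate 1). For control over time (1494) it was 2739 with all libraries, 929 with a fold of at least 1.5, 610 at an adjusted p under 0.01, 44 within replicates 1 and 2, and 791 (without 3 h control replicate 3) to 1600.

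Between doses at 3 h (0 by edgeR; 1385 at an unadjusted p under 0.05) the count was 4 with DESeq2, 1 without a filter, 3 with the replicate block, 3 with the replicate split term, and 0 without any 1 library. Between doses at 24 h (559) it was 843 with DESeq2 and 275 (without 1 µM replicate 1) to 593 without 1 library. For the change of the 10 µM effect (432) it was 673 with DESeq2 and 332 to 537 without 1 library. For the change of the 1 µM effect (6) it was 15 with DESeq2, 11 with the replicate split term, and 3 to 10 without 1 library (10 without 1 µM replicate 1 at 24 h).

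With an estimated correlation 0 lists were called in each of the 5 comparisons, also with the block or the replicate split term, where camera with its preset called 4, 10, 10, 12 and 22 lists (1 and 10 µM at 3 h, 1 and 10 µM at 24 h, and over time). The fry test called 0, 3, 2 and 7 in the first 4. With length and GC trends removed 2 lists were called for 1 µM at 3 h. Without 1 library the counts were 0 to 4 (0 without 1 µM replicate 4, 1 without 1 µM replicate 3 or control replicate 2, and 2 without control replicate 1), 7 to 15, 8 to 13, 11 to 15 and 21 to 26. At an adjusted p under 0.01, calls shared in direction by both doses at 24 h went from 12 to 6, and those shared by culture time and 10 µM from 251 to 110.

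Of the genes named or eligible to be named, 1 of 1 call at 10 µM and 3 h, 0 of 12 at 1 µM and 24 h, 3 of 99 at 10 µM and 24 h, and 12 of 123 over time were kept in every setting, with calls lost in 215 of 648 results within replicates 1 and 2, 61 of 644 within replicates 3 and 4, and 412 of 5736 without 1 library. At 10 µM and 24 h Ptch1 was kept in all 20 settings, while Gli1, Ihh and Hhip lost 1 of 20, with adjusted p-values up to 0.0524, 0.0867 and 0.225.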

Other observations

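The tests of the 3 h state and of shared culture change were chosen after the result was seen. In control cultures, 24 h brought fewer transcripts of dividing cells and of the integrated stress response (adjusted p = 0.114 for the G2/M and the stress response lists with an estimated correlation). With 10 µM BPDP, cell cycle genes were lower still than in the 24 h controls (adjusted p = 0.0535 for G2/M and 0.151 for G1/S with an estimated correlation), and stress response genes were higher (adjusted p = 0.223 with an estimated correlation). A delay of the cultures at the 3 h state would leave these genes near their 3 h levels. In 10 µM at 24 h against control at 3 h, the G2/M list had a median log2 change of -1.69 (-2.03 to -1.41 over 22 genes). This argues against a delay for the G2/M genes, but it follows from the falls over time and with 10 µM and is no separate test. Of 16 stress response genes 7 were higher and 3 lower (median 0.26), which does not decide the question for them.

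A general push along the path of culture time may also be asked about. Of 352 genes called both over time and with 10 µM at 24 h, 251 went the same way (66 higher and 185 lower) and 101 opposite, a share of 71.3%. Independent calls would give 23.6 higher, 22.1 lower and 47.2 opposite. The fold changes correlate at -0.269 because both comparisons use the same 24 h controls, where the simulations gave -0.502. With those controls split between the comparisons the share was 73.3 to 82.5%, on both sides of the bound of 80%, which was amended after the share was seen, so a shared change with culture time cannot be told apart from separate effects for these genes.

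At 24 h Ihh transcript rose at both doses while 3 of 8 hedgehog targets fell with 1 µM and 5 of 8 with 10 µM, where Foxf2 rose (target list, adjusted p = 0.0638 and 0.106 with an estimated correlation). Pthlh, which hedgehog signalling is known to maintain near the joints, fell with 10 µM (-1.47, adjusted p = 0.0011). Dhrs3 fell at both times with 10 µM (-1.07, adjusted p = 0.000183 at 3 h, and -0.82, adjusted p = 0.00889 at 24 h), and the change between times did not pass (0.26, adjusted p = 0.554). The macrophage and stress response lists were called at 24 h with 10 µM (adjusted p = 0.245 and 0.223 with an estimated correlation) and not with 1 µM, and the lists were not tested for the difference between doses. Among their genes C1qa (-2.48, adjusted p = 6.92e-08) and Trib3 (2.37, adjusted p = 3.19e-05) differed between the doses. Ptch1 did not pass that test (-0.30, adjusted p = 0.472), which does not exclude a difference.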
